A study of Mus musculus with 30 samples.

How the data were processed

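Poly-A RNA of whole mouse kidney, extracted with an RNeasy kit and sequenced as paired reads on a NovaSeq X Plus per the labels, was counted in 30 libraries. The groups were taken from the labels: genotype (WT or TG, named Gsta2-H2BeGFP), sex, and no surgery, nephrectomy (NX) or nephrectomy with ischemia-reperfusion injury (IRI) at 4 hours. The libraries were deposited as 2 count tables, 1 for the 12 no-surgery libraries and 1 for the 18 NX and IRI libraries. Per the submitters' processing notes the authors trimmed reads with fastp 0.23.2 and aligned them with STAR 2.7.0 to GRCm39 (mm39). Per the file headers they counted reads with featureCounts 2.0.3 over exons summed by gene, in the Ensembl release 112 annotation with an added EGFP entry. The deposited values are raw counts per gene, whole numbers without normalization. The option settings in the headers are not legible, so whether reads were counted by strand, as pairs, or when mapped to several places is not stated. Of the counts of 10 or more in a library 37.3 to 41.9% were odd, so most counts were even, as when both reads of a pair are counted; halved counts were therefore tried as an alternative.

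Each table holds 57133 genes by Ensembl identifier. Symbols were looked up by identifier in GENCODE M21, which may be older than the authors' annotation, and 51881 identifiers (90.8%) matched; 131 symbols belonged to more than 1 identifier, and genes without a symbol held 0.109% and 0.0831% of the reads. Positions are those of the deposited tables. Totals were 49040915 to 66446450 counts per no-surgery library and 59574069 to 91354407 per NX or IRI library. Where a group had 0 counts, folds were computed against a floor of 3 counts over the group and are lower bounds. Where both reads of a pair were counted, 3 counts stand for fewer than 3 read pairs, and these bounds are too high. Over all 435 pairs of libraries, no 2 were copies of each other by a chi-square comparison of their counts (18.51 to 603.95 per degree of freedom). All libraries were kept in the comparisons, including the library labelled WT IRI replicate 1, which holds EGFP counts.

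Differences were tested with the two-sided quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM normalization, filterByExpr and Benjamini-Hochberg adjusted p under 0.05. Comparisons of no-surgery libraries used a fit of all 12, with 1 coefficient per group. TG against WT after NX used its 6 libraries and after IRI its 12, and IRI against NX and the genotype by injury interaction used all 18. CPM are counts scaled by the TMM library sizes. The test was checked on simulated counts with the means and spread of these libraries, in which 200 genes of at least 1 CPM were changed. Of 100 genes changed 2-fold it recovered 76% (TG against WT, no-surgery male), 73% (NX), 84% (IRI) and 86% (IRI against NX). Of 100 changed 4-fold it recovered 97 to 99%, and it made 5 to 25 false calls. DESeq2 made 29 to 50 false calls. Simulated genes varied independently of each other. Where few genes differ the adjusted threshold is stricter, so recovery in the TG against WT comparisons may be lower. The 33 gene lists (pathways, cell types, sex-biased kidney genes, clock and sex chromosome genes) were tested with camera of limma 3.58.1 with its preset correlation of 0.01, again with a correlation estimated per list, and with fry, adjusted over the lists of a comparison; lists needed 3 measured members, and Gsta2 belonged to none. Per library, 10 lists were scored as the mean log2 CPM (prior count 2) of their members and compared between genotypes after IRI by exact two-sided permutation. Pearson and Spearman correlations of Gsta2 with 3 scores used exact permutation of pairings within each genotype. Genes sex-biased by at least 2-fold in WT, autosomal and without Gsta2, were tested with camera in TG against WT.

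The comparisons, tests, gene lists, the rule for named genes and the main alternatives were fixed before the data were examined. Named genes are Gsta2 first in every group; the 8 highest and 8 lowest changes among called genes with a symbol that is not a predicted gene and at least 1 CPM in the higher group, for TG against WT after IRI, IRI against NX in WT, females against males in WT and TG against WT in no-surgery males; the 4 highest and 4 lowest for the others; up to 4 members per list, or the 1 with the smallest p when none passed; always Havcr1, Lcn2, the sex chromosome genes and the alpha-class transferases; and genes called in all 3 male TG against WT comparisons. Where few genes were called, all were named except where a gene is not reported here, and Gm8730, Gm6969, the fat genes' library, the globin genes and the genes on chromosome 11 were chosen after their values were seen. Alternatives were relative log expression (RLE) and upper-quartile factors, no count filter, DESeq2 1.42.0 (Wald test), limma-voom with sample weights, a 2-fold minimum, replicate number as a block, other sets of libraries in the fit, robust edgeR, and leaving out each replicate in turn. Added after the data were seen were halved counts, the run of library numbers as a block, leaving out the libraries labelled WT IRI replicate 1 and WT NX replicate 0 from list tests, and the combination of 4 TG against WT comparisons by Stouffer's method on 16299 genes. Gsta13, Ddit3 and Bmal1 were not measured under those symbols.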

Results

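Poly-A RNA of whole mouse kidney was sequenced in 30 libraries. Wild-type (WT) kidneys were set beside kidneys of a transgenic genotype (TG) that the labels name Gsta2-H2BeGFP, and the counted annotation holds an added entry for EGFP, the green fluorescent protein. Without surgery there were 3 WT and 3 TG libraries of males and 3 WT and 3 TG libraries of females. After nephrectomy (NX), the removal of a kidney, there were 3 WT and 3 TG libraries, all of males. After nephrectomy with ischemia-reperfusion injury (IRI), in which the blood supply of the kidney is stopped and restored, there were 6 WT and 6 TG libraries of males, taken 4 hours after injury. The labels do not state when the NX kidneys were taken. Total counts ran from 49040915 to 66446450 in the 12 no-surgery libraries and from 59574069 to 91354407 in the 18 others, and 20969 to 24070 genes had a count. Levels below are means ± SD in CPM, counts scaled to a common library size, and changes are log2 fold changes ± SE from edgeR. Replicates are numbered from 0, and the labels do not say whether each library came from a separate animal, so p-values measure the spread between these libraries.

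Gsta2 encodes an alpha-class glutathione S-transferase, a detoxifying enzyme that joins glutathione to reactive compounds, and the series title calls it female-biased. It lies on chromosome 9 of GRCm39 (ENSMUSG00000057933, 78238300 to 78263070, minus strand). Without surgery its level was 96.2 ± 8.38 CPM in WT males, 50.6 ± 18.6 in TG males, 322 ± 27.3 in WT females and 324 ± 27.3 in TG females (n = 3 each). After NX it was 70 ± 11.9 in WT and 111 ± 61.8 in TG libraries (n = 3 each), with 182 CPM in TG replicate 1 and 73.4 and 77.6 in the others. After IRI it was 84.6 ± 34 in the libraries labelled WT and 77.2 ± 9.7 in TG libraries (n = 6 each). None of the TG against WT differences passed the edgeR test. They were -0.92 ± 0.19 without surgery in males (adjusted p = 0.673), 0.01 ± 0.18 in females (adjusted p = 0.999), 0.64 ± 0.32 after NX (adjusted p = 0.749) and -0.14 ± 0.2 after IRI (adjusted p = 0.806). The range of 2 SE around these estimates ended at -0.55, 1.29 and 0.27 in no-surgery, NX and IRI males. Its near-identical paralogs Gsta1, Gm10639 and Gm3776 together held at most 7.95% of the summed CPM of these genes and Gsta2 in any group of males, and at most 11.1% in any male library.

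EGFP had 0 counts in every WT library but 1, so its folds are lower bounds against a floor of 3 counts over the WT group. It was at least 372-fold higher in TG than in WT males without surgery (6.82 ± 1.75 CPM, n = 3, adjusted p = 0.000285), at least 871-fold higher in females (14.9 ± 3.45, n = 3, adjusted p = 8.92e-05) and at least 238-fold higher after NX (3.68 ± 0.846, n = 3, adjusted p = 0.00394). In TG libraries after IRI it was 2.82 ± 1.93 CPM (n = 6). The library labelled WT IRI replicate 1 held 206 EGFP counts, or 2.59 CPM, inside the range of the TG IRI libraries (1.17 to 6.31), and the TG against WT difference after IRI was 2.67 ± 1.16 (adjusted p = 0.326). EGFP was also higher in TG females than in TG males (1.12 on the log2 scale, adjusted p = 0.00955). Genes of the sex chromosomes matched the labels: Xist, the X-inactivation RNA, was at 313 to 428 CPM in the female libraries, and the Y-linked RNA helicase gene Ddx3y was at 0 in all of them. Xist was at 4.82 CPM in WT male no-surgery replicate 0. Floors cover counting error only, whereas the SE cover the spread between libraries. They also take each count as 1 read pair. All EGFP counts were even, and if both reads of a pair were counted, these lower bounds are too high.

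**Figure D1:**
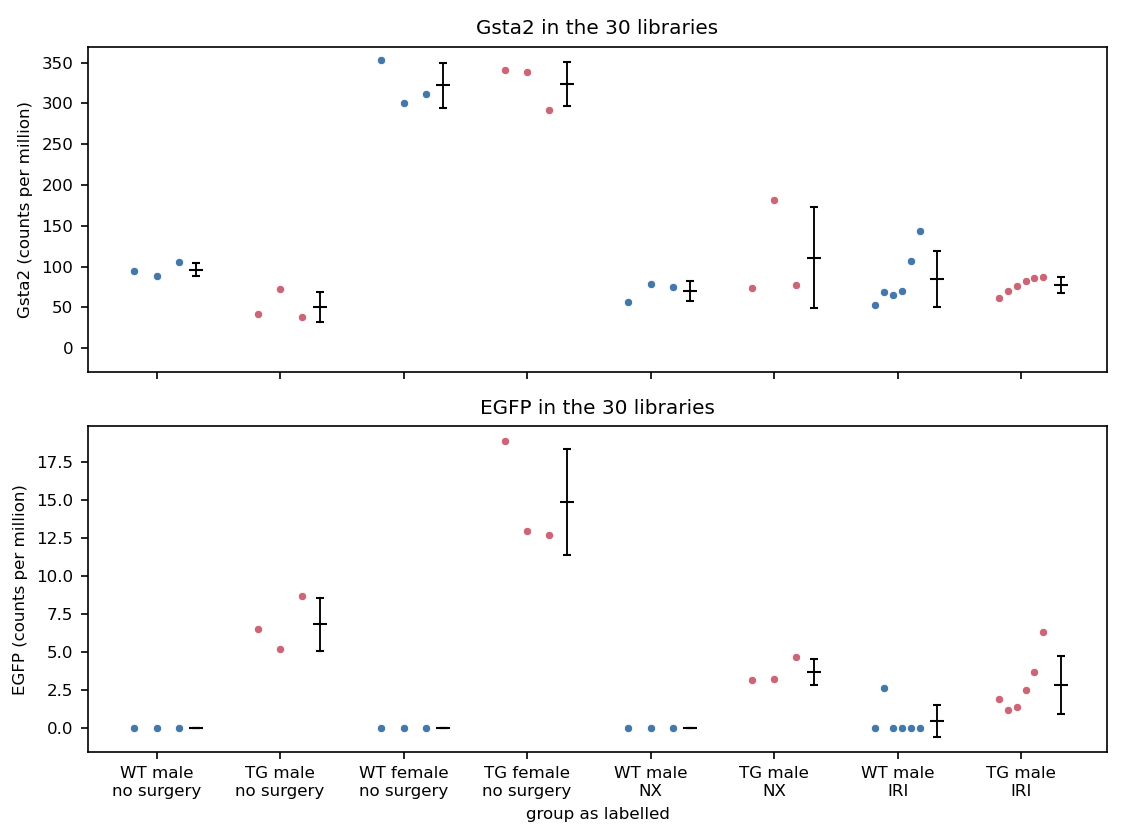
Gsta2 (top) and EGFP (bottom) in CPM (linear axes) by group, with a point for each of the 30 libraries and black marks for the group mean ± SD. Gsta2 was highest in both female groups (322 and 324 CPM), and the library labelled WT IRI replicate 1 held 2.59 CPM of EGFP.

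The comparison of TG with WT males without surgery asks what the transgene changed in uninjured male kidneys. EGFP rose, and edgeR called no other gene among 19126 tested. The other alpha-class transferases were close between the groups, with Gsta3 at 80.1 ± 8.49 CPM in TG and 81.3 ± 11 in WT and Gsta4 at 21.2 ± 2.85 and 23.1 ± 0.144. Gsta2 itself lay lower in all 3 TG than in all 3 WT libraries (-0.92 ± 0.19), without passing the test adjusted over 19126 genes. Chance gives such a separation of ranks to 10% of genes, whatever the size of their change. Gsta2 was the gene named first beforehand, and the range of 2 SE around its change ended at -0.55, below 0. Lcn2, the injury-induced gene of the iron-carrier-binding protein lipocalin 2, was at 4.63 ± 2.46 and 3.77 ± 1.25 CPM (adjusted p = 0.954). At an unadjusted p under 0.05 there were 998 genes, 5.2% of those tested, near the share of 0.05 that chance gives. DESeq2 called 14 genes and limma-voom 0. Of 33 gene lists, camera called 8 with its preset correlation (6 higher, 2 lower) and 0 with an estimated correlation; cell cycle genes, the list with the smallest p, were higher with adjusted p = 8.84e-05, against adjusted p = 0.543 with an estimated correlation.

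In females without surgery, 8 genes differed between TG and WT. Beside EGFP, Rgl1, an exchange factor of Ral GTPases (171 ± 6.22 against 95.6 ± 4.22 CPM, adjusted p = 0.0139), Pitpnc1, a phosphatidylinositol transfer protein (69.2 ± 4.69 against 42.6 ± 4.6, adjusted p = 0.0139), and Fndc3a (130 ± 4.01 against 95.9 ± 3.43, adjusted p = 0.0378) were higher in TG libraries. Insig1, a sterol sensor, fell 1.91-fold (34.8 ± 4.66 against 66.3 ± 6.33, adjusted p = 0.0139) and Msmo1, an enzyme of cholesterol synthesis, 1.67-fold (27.6 ± 1.11 against 46 ± 3.56, adjusted p = 0.0091). Slc45a3, a sugar transporter, fell 2.24-fold (41.2 ± 4.38 against 92.4 ± 8.34, adjusted p = 0.0239; n = 3 in each group throughout). Only Msmo1 passed the test of whether the genotype difference differed between the sexes (-0.98 ± 0.12, adjusted p = 0.0363); for Gsta2 this interaction was 0.93 ± 0.26 (adjusted p = 0.395). Proximal tubule genes were higher as a list with adjusted p = 0.00361, against adjusted p = 0.866 with an estimated correlation. The count of 8 depended on single libraries: it was 1 without WT female replicate 0 or 2, 22 without WT female replicate 1 and 4 without TG female replicate 2. WT female replicate 1 held the adipocyte hormone gene Adipoq at 25.63 CPM, against 2.045 and 1.264 in the other WT females. In TG females it was at 1.719 to 10.28 CPM, and whether it bears on the count was not tested. DESeq2 called 220 genes and limma-voom 73.

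The comparison of females with males asks which kidney genes are sex-biased, and it changed far more genes than genotype. In WT libraries (n = 3 in each sex) Gsta2 was 3.35-fold higher in females (1.74 ± 0.19, adjusted p = 3.96e-05). Its relatives were higher too. Gsta4, which detoxifies lipid aldehydes, was 4.9-fold higher (113 ± 11.7 against 23.1 ± 0.144 CPM, adjusted p = 1.67e-07). Gsta1 was 5.15-fold higher at a low level (1.22 ± 0.215 against 0.236 ± 0.128), and as a near-identical paralog it may hold reads of Gsta2. Gsta3 was 1.4-fold higher (114 ± 10.7 against 81.3 ± 11, adjusted p = 0.0187), but it did not pass without WT female replicate 0 or WT male replicate 1 or 2. Ugt1a2, of the enzyme family that joins glucuronic acid to drugs and bilirubin, was at 454 ± 20.3 CPM in females and 1.26 ± 1.02 in males (adjusted p = 4.33e-08). The organic anion transporter Slco1a1 was at 0.0114 ± 0.00989 in females and 356 ± 119 in males (adjusted p = 1.96e-09), and the amino acid transporter Slc7a13 at 2.31 ± 1.11 and 774 ± 29.1 (adjusted p = 6.96e-09). Other genes at the extremes were Myh1, Tmprss6, Cited1, Ptpn5 and Serpina6, higher in females, and Pzp, lower. Ifi202b was at least 79.8-fold higher in females, Mpped1 at least 440-fold lower, and the Y-linked Ddx3y, Eif2s3y, Uty and Kdm5d at least 3690, 2780, 2070 and 1110-fold lower.

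Of 7 genes listed beforehand as female-biased in kidney, 6 were higher in WT females (6 higher and 1 lower adjusted over the list alone). They included Slc7a12, an amino acid transporter (302 ± 54.2 against 11.9 ± 2.78 CPM), and Abcc3, an exporter of organic anions (179 ± 35.8 against 3.05 ± 1.11). Of 16 male-biased genes 14 were lower in females (15 adjusted over the list alone), while Serpina1f was higher (219 ± 41.7 against 118 ± 19.8; not past the threshold without WT male replicate 0). Both lists kept their camera call with an estimated correlation (adjusted p = 0.00076 and 0.000332). Markers of distal nephron segments were higher in females. All 7 genes of the distal convoluted and connecting tubule rose, over all genes and adjusted over the list alone, among them the calcium-binding protein gene Calb1 (770 ± 69.3 against 351 ± 30.8) and the magnesium channel gene Trpm6 (39.2 ± 2.95 against 19.9 ± 1.84), with adjusted p = 0.00299 with an estimated correlation. Of 11 collecting duct genes 10 rose, and 11 adjusted over the list alone (adjusted p = 0.0229 with an estimated correlation). They included the sodium channel subunit gene Scnn1g (80.6 ± 4.54 against 41.1 ± 4.9) and the water channel gene Aqp2 (771 ± 212 against 333 ± 109, not past the threshold without WT female replicate 2).

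Other groups moved by count but lost their camera call with an estimated correlation. Of 23 proximal tubule genes 3 were higher and 10 lower in females (6 and 12 adjusted over the list alone; adjusted p = 0.478 with an estimated correlation), with the organic anion transporter gene Slc22a6 at 382 ± 20 against 1030 ± 190 CPM and the acyl-CoA synthetase gene Acsm2 at 1400 ± 51.7 against 5450 ± 569. Of 23 glutathione S-transferases 10 were higher and 2 lower (10 and 3 adjusted over the list alone; adjusted p = 0.101 with an estimated correlation). Of 18 targets of the oxidative stress regulator NRF2 1 was higher and 8 lower (1 and 8 adjusted over the list alone; adjusted p = 0.253 with an estimated correlation), among them Me1, which makes NADPH (289 ± 6.62 against 644 ± 96), and the haem-degrading enzyme gene Hmox1 (13.4 ± 1.04 against 27.7 ± 7.94), which did not pass without WT female replicate 1 or 2 or WT male replicate 0. Of 7 podocyte genes 5 were higher and 7 adjusted over the list alone (adjusted p = 0.235 with an estimated correlation). Of 14 circadian clock genes 7 were higher and 3 lower (9 and 3 adjusted over the list alone), with Cry1 at 11.4 ± 1.15 against 2.55 ± 0.497 and Npas2 at 1.11 ± 0.116 against 5.53 ± 1.24; the labels give no hour of collection.

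In all, edgeR called 1923 genes higher and 2154 lower in WT females of 19126 tested, of which 403 and 468 by at least 2-fold. In TG libraries it called 1888 and 2166. Of these, 1101 were higher in both genotypes (190 were the number for unrelated sets of these sizes) and 1477 lower in both (244). The calls went higher in WT and lower in TG for 3 genes and the other way for 3. The comparisons share no compared library but come from the same fit with a shared estimate of spread, so the calls are not fully independent. In TG libraries Gsta2 was 6.38-fold higher in females (2.67 ± 0.2, adjusted p = 2.01e-06), Gsta4 4.55-fold (adjusted p = 2.36e-07), Slc7a12 56.2-fold (325 ± 25.6 against 5.78 ± 1.36 CPM) and Ugt1a2 868-fold (418 ± 44.9 against 0.476 ± 0.227). The epoxygenase gene Cyp2j13 was lower (0.647 ± 0.326 against 295 ± 73.1). The female-biased, male-biased and distal convoluted and connecting tubule lists kept their calls in TG libraries (adjusted p = 0.0015, 0.000611 and 0.0114 with an estimated correlation), and the collecting duct list gave adjusted p = 0.0532.

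**Figure D2:**
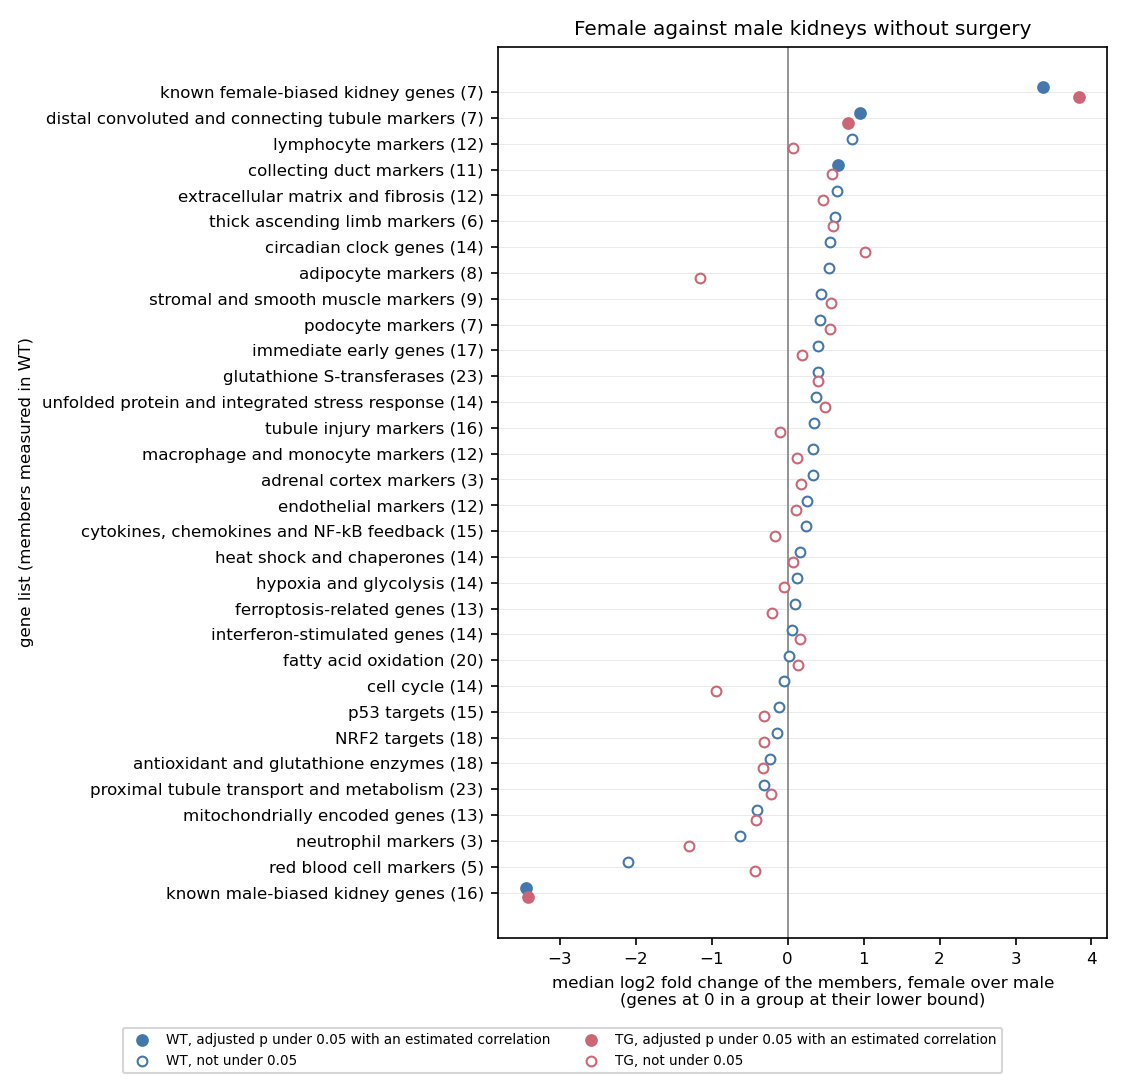
Median log2 fold change (females against males without surgery) of each gene list in WT and in TG libraries, with genes at 0 in a group placed at their lower bound and the sex chromosome list left out; filled points mark an adjusted p under 0.05 with an estimated correlation. The female-biased, male-biased and distal convoluted and connecting tubule lists are filled in both genotypes, with 6 of 7, 14 of 16 and 7 of 7 members called in WT.

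After NX the comparison of TG with WT asks about genotype in male kidneys labelled nephrectomy without ischemia-reperfusion injury. EGFP rose, and the predicted gene Gm8730 (chromosome 8, 103591477 to 103592430) fell from 42.8 ± 4.1 CPM in WT to 1.67 ± 0.0628 in TG libraries (adjusted p = 5.88e-07, n = 3 each). Havcr1, the gene of kidney injury molecule 1, was at 0.789 ± 0.353 in TG and 0.971 ± 0.547 in WT, and Lcn2 at 1.94 ± 0.336 and 0.932 ± 0.308 (adjusted p = 0.919 and 0.73). edgeR called these 2 of 17100 genes, with 1157 (6.8%) at an unadjusted p under 0.05, against 45 by DESeq2 and 2 by limma-voom. Of the gene lists camera called 6 (1 higher, 5 lower), and 0 with an estimated correlation. WT NX replicate 0 held the adipocyte hormone gene Adipoq at 35.0 CPM, which was at 0 in the other 2 WT NX libraries. Without this library edgeR called 15 genes. Without surgery Adipoq was at 25.63 CPM in WT female replicate 1 and 25.1 in TG male replicate 1, so it was not confined to NX replicate 0. Without TG NX replicate 0 or 1 or WT NX replicate 1 the counts were 6, 5 and 6.

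The comparison of IRI with NX asks how kidneys 4 hours after injury differed from NX kidneys, whose time of collection is not stated. In WT libraries (6 IRI against 3 NX) early response genes were the most raised. The transcription factor genes Fos (430 ± 111 against 0.37 ± 0.0769 CPM), Fosb (428 ± 109 against 0.258 ± 0.167) and Atf3 (688 ± 146 against 0.594 ± 0.408) rose 1140, 1630 and 1140-fold. The neutrophil attractant gene Cxcl2 and the cytokine gene Il6, both at 0 in NX, rose at least 516 and 426-fold, and Vgf, Acod1 and Nptx2 at least 244, 244 and 132-fold. Lcn2 rose 20.9-fold (19.8 ± 8.77 against 0.932 ± 0.308, adjusted p = 2.03e-08), whereas Havcr1 was at 1.51 ± 0.612 and 0.971 ± 0.547 (adjusted p = 0.366). Gsta2 did not pass (0.25 ± 0.28, adjusted p = 0.545), and Gsta3 fell 1.37-fold (70.8 ± 8.06 against 96.1 ± 4.14, adjusted p = 0.0137; not past the threshold without WT NX replicate 2).

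All 18 immediate early genes rose in WT libraries, as they did adjusted over the list alone (adjusted p = 1.12e-07 with an estimated correlation). Of 17 tubule injury markers 15 rose over all genes and adjusted over the list alone, among them the keratin gene Krt20 (52.1 ± 46.1 against 1.5 ± 2.46 CPM) and the growth factor gene Areg (1.09 ± 0.444 against 0, at least 70.8-fold). Of 18 cytokine, chemokine and NF-kB feedback genes 17 rose on both counts, and of 15 p53 targets 9 rose and 2 fell (10 and 2 adjusted over the list alone), with the cell cycle inhibitor gene Cdkn1a at 109 ± 13.4 against 4.45 ± 2.59 and Gdf15 at 82.1 ± 15.7 against 3.05 ± 0.647. These 3 lists had adjusted p = 0.000342 with an estimated correlation. Of 14 genes of the unfolded protein and integrated stress response 10 rose and 1 fell on both counts (adjusted p = 0.0407 with an estimated correlation), led by the glutathione-degrading enzyme gene Chac1 (21.4 ± 10.6 against 0.286 ± 0.252) and Ppp1r15a (118 ± 13.2 against 5.84 ± 0.381). Of 14 heat shock genes 12 rose, and 14 adjusted over the list alone (adjusted p = 0.0746 with an estimated correlation); Hspa1a, a stress-induced Hsp70 chaperone, went from 33.4 ± 41.2 to 1550 ± 423. All 8 neutrophil markers rose on both counts (adjusted p = 0.118 with an estimated correlation), as did all 5 red blood cell markers (adjusted p = 0.463 with an estimated correlation).

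Genes of tubule function fell in part. Of 23 proximal tubule genes 9 fell in WT libraries on both counts (adjusted p = 0.339 with an estimated correlation), with the endocytic receptor genes Lrp2 at 1420 ± 400 against 2790 ± 802 CPM and Cubn at 352 ± 61 against 631 ± 191. Of 20 fatty acid oxidation genes 8 fell and Pdk4 rose (1 and 9 adjusted over the list alone; adjusted p = 0.339 with an estimated correlation). Of 21 glutathione S-transferases 3 rose and 8 fell (3 and 10 adjusted over the list alone; camera adjusted p = 0.0595), with Gstm1 at 243 ± 35.4 against 417 ± 48.7. Among NRF2 targets the sulfiredoxin gene Srxn1 rose 5.44-fold and Nqo1 fell 1.6-fold. The clock gene Arntl was at 8.03 ± 2.22 against 0.578 ± 0.165, beside the unstated collection time of the NX kidneys. The largest falls were in fat genes and came from the single library WT NX replicate 0: Ucp1, the uncoupling protein of brown fat, was at 213 ± 369 CPM in NX, and its change of -5.64 ± 2.1 turned to 11.28 without that library, as Elovl3, Orm1, Adrb3, Plin1, Otop1, Cidec and Acvr1c turned as well.

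edgeR called 3229 genes higher and 2723 lower after IRI in WT libraries of 19264 tested (1627 and 467 by at least 2-fold), and 3152 and 2509 in TG libraries. Of these, 2334 were higher in both (528 were the number for unrelated sets) and 1499 lower in both (355). The change was higher in WT and lower in TG for 2 genes, and the reverse for 2. Here too both comparisons come from the same fit with a shared estimate of spread. In TG libraries the AP-1 gene Fosl1 rose at least 852-fold, Cxcl2 at least 373-fold, Il6 at least 275-fold and the matrix protease gene Mmp10 at least 269-fold. Havcr1 rose 8.71-fold (6.88 ± 4.51 against 0.789 ± 0.353 CPM, adjusted p = 0.000216), Lcn2 13.1-fold (25.3 ± 4.56 against 1.94 ± 0.336), and all 17 tubule injury markers rose, over all genes and adjusted over the list alone (adjusted p = 0.000105 with an estimated correlation). The lists of immediate early, cytokine, p53 and stress response genes kept their calls there too (adjusted p = 2.36e-07, 0.000824, 0.000401 and 0.0133 with an estimated correlation). Of 13 ferroptosis-related genes 8 rose and of 14 hypoxia and glycolysis genes 5 rose in TG libraries, on both counts (adjusted p = 0.00857 and 0.0193 with an estimated correlation). Cyp4a14 had the change -3.29 ± 0.94, which turned to 0.27 without TG NX replicate 1. edgeR called 0 genes for a genotype difference in the injury response, with 1848 (9.6%) at an unadjusted p under 0.05. DESeq2 called 51 and limma-voom 0. This difference was 2.5 ± 0.68 for Havcr1 (edgeR adjusted p = 0.376) and -0.77 ± 0.4 for Gsta2 (edgeR adjusted p = 0.562). Camera called 12 of the lists for this interaction and 0 with an estimated correlation.

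**Figure D3:**
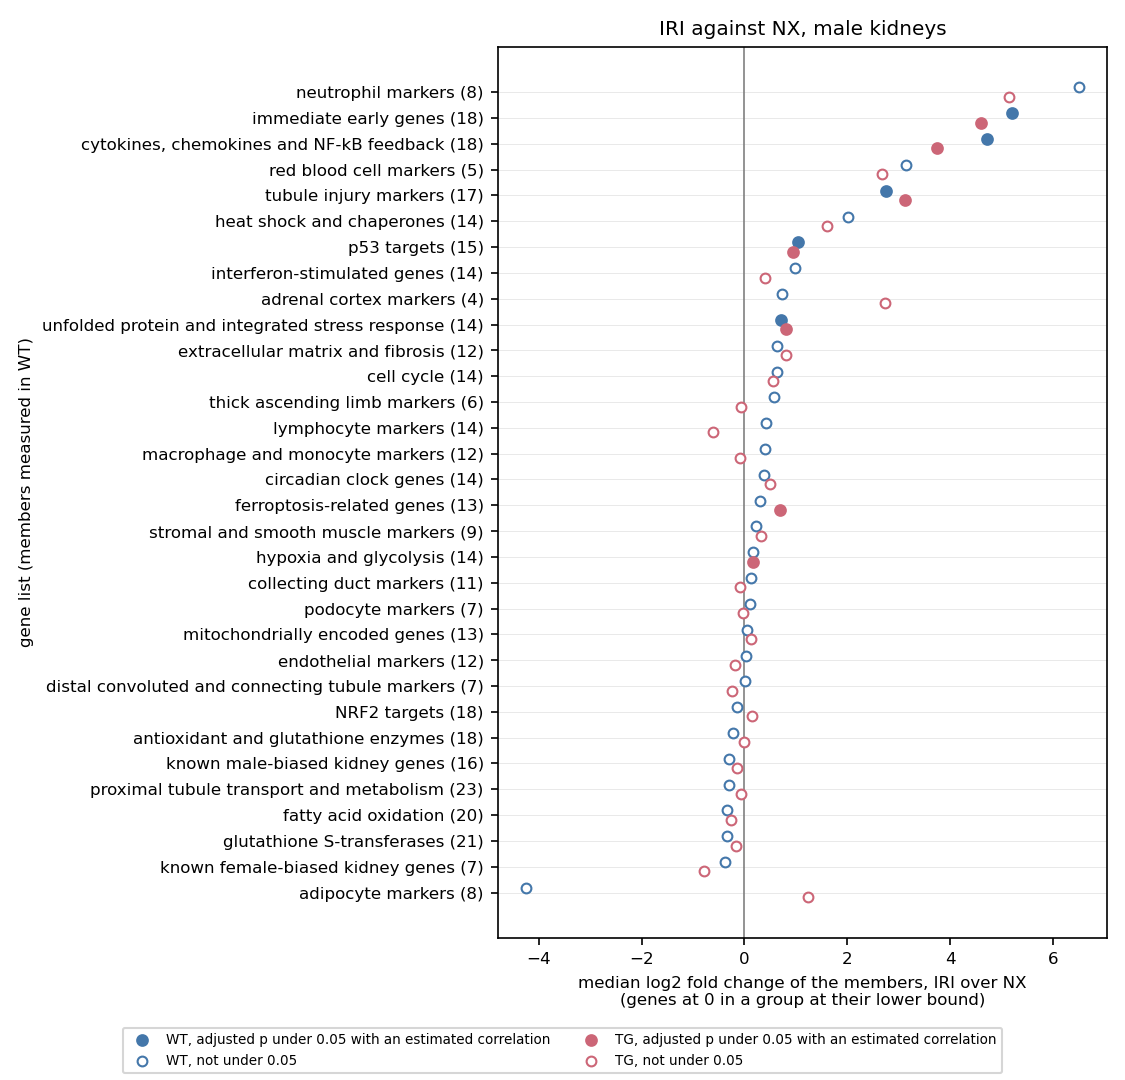
Median log2 fold change (IRI against NX, males) of each gene list in WT and in TG libraries, with genes at 0 in a group placed at their lower bound and the sex chromosome list left out; filled points mark an adjusted p under 0.05 with an estimated correlation. The lists of immediate early, tubule injury, cytokine, p53 and stress response genes are filled in both genotypes, with 18 of 18, 15 of 17, 17 of 18, 9 of 15 and 10 of 14 members higher in WT.

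The comparison of TG with WT after IRI is the series' stated question, how the transgenic kidney differs early after injury. Havcr1 (chromosome 11, 46625907 to 46670405), a marker of injured proximal tubule, was 4.54-fold higher in TG libraries, at a low level (6.88 ± 4.51 against 1.51 ± 0.612 CPM, n = 6 each, 2.18 ± 0.37). Immediate early genes were lower: Jun 2.57-fold (413 ± 107 against 1060 ± 368), Fos 2.15-fold (200 ± 41.8 against 430 ± 111) and Junb 1.46-fold (128 ± 14.2 against 186 ± 21.2). The stress-induced Hsp70 genes Hspa1a (532 ± 214 against 1550 ± 423) and Hspa1b (753 ± 326 against 2060 ± 480) were 2.92 and 2.73-fold lower; their sequences are nearly the same, so reads can pass between them. Also lower were the matricellular signalling gene Ccn1 (432 ± 37.1 against 774 ± 145), the p53-induced kinase gene Plk2 (55.9 ± 9.04 against 85.6 ± 8.11), Rnd3 (102 ± 18.4 against 168 ± 24.4), Apold1 (20.3 ± 2.67 against 34.9 ± 6.83), Arl4c (31.6 ± 4.32 against 54 ± 9.45) and Gas1 (11 ± 1.65 against 20.4 ± 4.73). edgeR called these 12 of 17111 genes, each with adjusted p = 0.0435, against 363 calls by DESeq2 and 15 by limma-voom. By edgeR 2413 genes (14.1%) had an unadjusted p under 0.05. Lcn2 was at 25.3 ± 4.56 against 19.8 ± 8.77 (adjusted p = 0.488) and Hmox1 at 421 ± 85.8 against 227 ± 84.3 (adjusted p = 0.126).

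These calls lay near the threshold. No gene passed without TG replicate 0, 2, 3 or 5 or without WT replicate 0, 4 or 5, and 19, 35 and 109 genes passed without TG replicate 4, WT replicate 2 and WT replicate 3. Without the library labelled WT IRI replicate 1, which holds EGFP, 8 genes passed, 6 of them among the 12. The library numbers of the IRI samples fall into 3 runs, with 3 WT and 2 TG, 1 WT and 3 TG, and 2 WT and 1 TG libraries. With run as a block no gene passed, Hspa1a changing from -1.55 ± 0.24 to -1.42 ± 0.25, Fos from -1.1 ± 0.17 to -1.04 ± 0.17 and Havcr1 from 2.18 ± 0.37 to 1.79 ± 0.3. Within the runs, of which 2 rest on a single library of a genotype, the difference was -1.17, -1.69 and -1.93 for Hspa1a, -0.85, -1.05 and -1.28 for Fos, and 1.33, 1.95 and 2.2 for Havcr1.

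**Figure D4:**
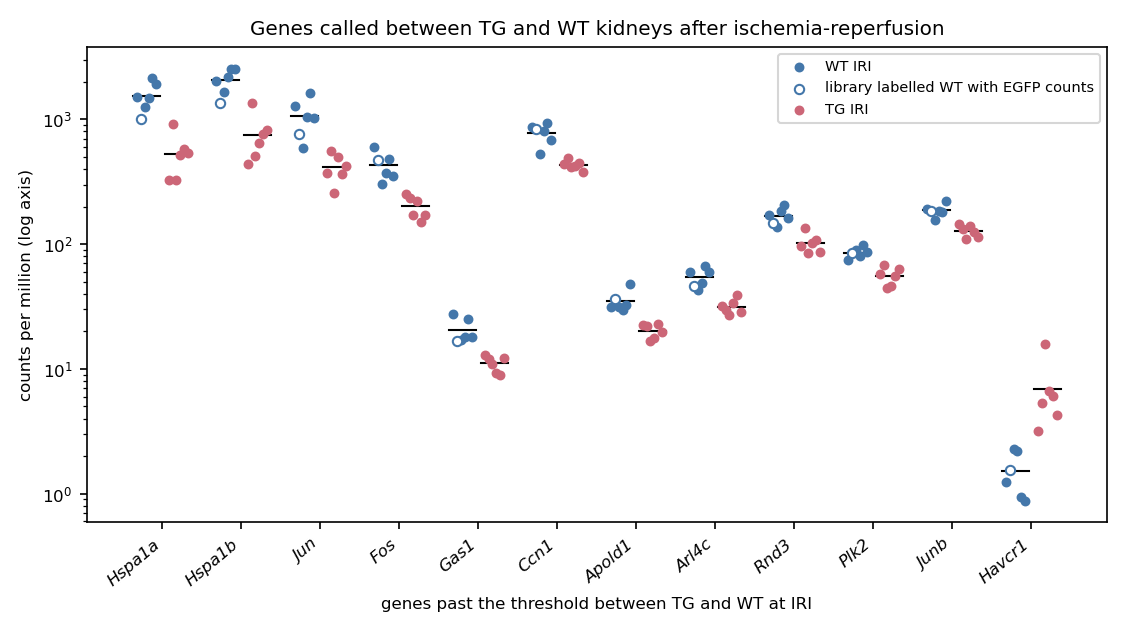
Levels in CPM (log axis) of the 12 genes called between TG and WT after IRI, with a point for each of the 12 libraries and black lines for group means. Havcr1 is higher and the 11 others are lower in TG libraries, and the library labelled WT that holds EGFP is an open point.

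As groups, 3 of 18 immediate early genes were lower in TG libraries after IRI and none higher, with 14 lower and 1 higher adjusted over the list alone. Theirs was the only list to keep its camera call with an estimated correlation (adjusted p = 0.0243). Its mean log2 CPM per library was 6.67 ± 0.18 in TG and 7.18 ± 0.12 in libraries labelled WT, lower in 6 of 6 TG libraries than in any WT library (adjusted p = 0.0216, two-sided exact permutation test over 10 lists; the unadjusted p of 0.00216 is the smallest this test can give). Of 14 heat shock genes 2 were lower, and 5 adjusted over the list alone (adjusted p = 0.274 with an estimated correlation); the list's score differed by -0.49 (exact permutation, adjusted p = 0.0505), with 5 of 6 TG libraries below all WT. Of 8 neutrophil markers 5 were lower adjusted over the list alone and none over all genes (adjusted p = 0.345 with an estimated correlation), with a score difference of -1.48 (exact permutation, adjusted p = 0.0505). Tubule injury markers had 1 higher gene, with 3 higher and 1 lower adjusted over the list alone (adjusted p = 0.432 with an estimated correlation) and a score difference of 0.32 (exact permutation, adjusted p = 0.0606). NRF2 targets, of which 2 were higher adjusted over the list alone, differed in score by 0.16 (exact permutation, adjusted p = 0.0606), and the scores of proximal tubule, fatty acid oxidation and glutathione S-transferase genes by -0.04, 0.06 and -0.04 (exact permutation, adjusted p = 0.604, 0.604 and 0.634). Camera with its preset correlation called 18 lists, 4 higher and 14 lower. The lower ones included markers of endothelial cells (adjusted p = 0.00165), podocytes (0.00089), lymphocytes (0.00089), macrophages (0.00676), the thick ascending limb (0.0115) and the collecting duct (0.0246), which with an estimated correlation had adjusted p = 0.371 to 0.505. Red blood cell markers were lower too (adjusted p = 0.0898 with an estimated correlation). In a test chosen after the values were seen, 4 globin genes summed to 61.8 ± 44.7 CPM in TG and 474 ± 416 in libraries labelled WT. By exact permutation of the summed log2 level p was 0.00433, and 0.0173 adjusted over 4 TG against WT comparisons, not over the 10 lists. The share of mitochondrial counts was 15.02% and 16.27% in the libraries labelled WT replicates 4 and 5 and 9.52 to 11.13% in the other IRI libraries.

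Whether IRI libraries with more Gsta2 had lower injury scores was asked in 6 relations within genotypes, and none passed. In the 6 TG libraries Gsta2 and the tubule injury score had a Pearson r of -0.41 and a Spearman coefficient of -0.54 (exact permutation, p = 0.407 and 0.297; adjusted p = 0.912 for r). In the 6 libraries labelled WT r was -0.08 and the Spearman coefficient 0.09 (exact permutation, p = 0.878 and 0.919), and r was 0.88 without the 2 libraries farthest from the median. The largest r was that of Gsta2 with neutrophil markers in libraries labelled WT (r = 0.79, Spearman coefficient 0.77, exact permutation, p = 0.0514 and 0.103, adjusted p = 0.308 for r); it was 0.28 without WT replicates 4 and 5, so it rested on those libraries. Sex-biased genes taken from WT no-surgery libraries were then followed in TG against WT males. The 386 female-higher genes gave adjusted p = 0.223 after NX and 0.192 after IRI by camera, and the 459 male-higher genes gave adjusted p = 0.223 after NX. After IRI 283 of 425 tested male-higher genes (66.6%) had a positive change, with a median of 0.113 (adjusted p = 3.8e-05, but adjusted p = 0.538 with an estimated correlation).

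Across conditions, the TG against WT calls shared EGFP between males without surgery and after NX and between the sexes without surgery, and no gene was called in all 3 male comparisons (9.03e-08 genes were the number for unrelated sets among 16299). In a test added after these results were seen, the 4 TG against WT comparisons without shared libraries were combined. Those of no-surgery males and females share an estimate of spread. Beside EGFP 3 genes were called, and they lie within a stretch of chromosome 11. Sfi1, a centrosome protein gene (3081850 to 3143463), was higher by 0.64, 0.84, 0.46 and 0.67 in no-surgery males, NX, IRI and females (combined adjusted p = 4.04e-08). Patz1, a zinc finger transcription factor gene (3238874 to 3259083), was higher by 0.48, 0.55, 0.36 and 0.27 (combined adjusted p = 2.01e-07), and the predicted gene Gm12735 (3143516 to 3144263) by 3.43, 2.71, 1.79 and 1.94 (combined adjusted p = 0.000614). The other tested genes there, Gm11400, Drg1 and Eif4enif1, had combined adjusted p = 0.769, 0.968 and 0.415. On the minus strand Gm11400 lies inside Sfi1 and Gm12735 inside Drg1, which also overlaps Sfi1, and the files do not state how reads in overlaps were counted.

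**Figure D5:**
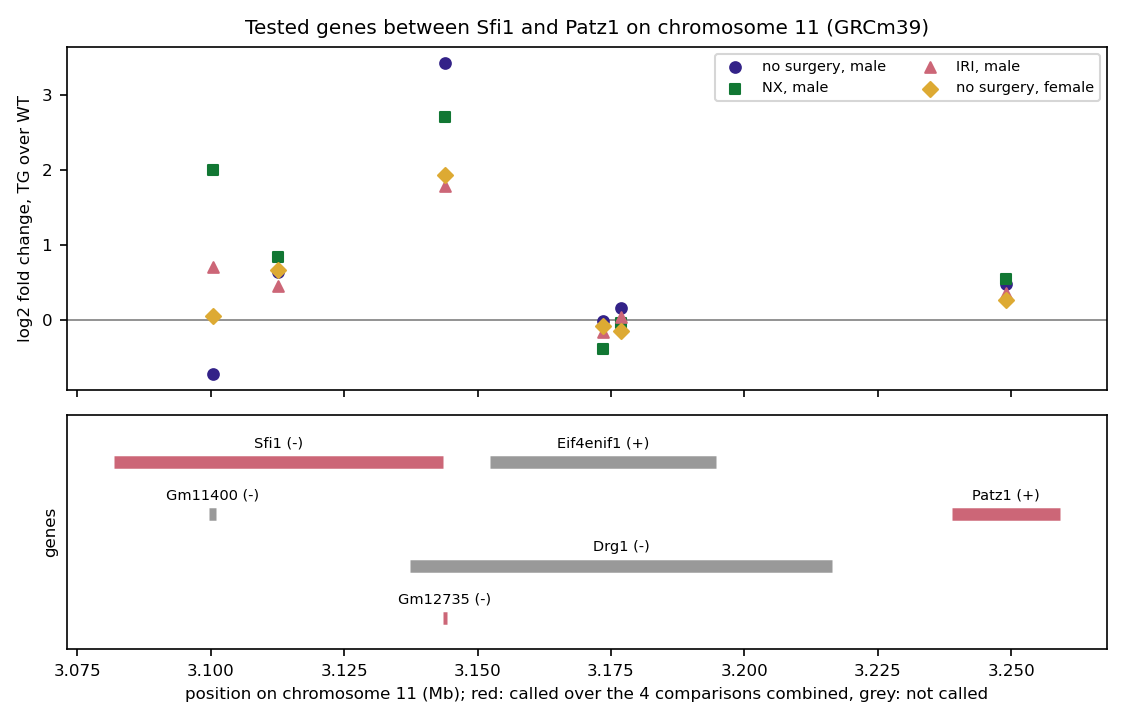
Log2 fold change (TG against WT) of the tested genes from Sfi1 to Patz1 in 4 comparisons (top), by position on chromosome 11 of GRCm39 in Mb, and the extent and strand of each gene (bottom), in red where called over the comparisons combined. Sfi1, Gm12735 and Patz1 are higher in TG in all 4, while Drg1 lies between -0.14 and 0.17.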

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

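The tests of the EGFP counts, of the Gsta2 level and of the lower early genes were chosen after these results were seen, whereas the counts of other splits were planned.

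The library labelled WT IRI replicate 1 held EGFP at 2.59 CPM, far from the 0 of the 5 other WT IRI libraries. Traces of reads from TG libraries are argued against by the size of the signal, 91.9% of the mean of the TG IRI libraries. Whether a wrong label may be the source stays open, since the values go both ways: of 5 genes called when the 3 other TG against WT comparisons were combined, 3, all in a stretch of chromosome 11, separated the TG from the other WT IRI libraries, and at 3 of these 3 it lay inside the TG range (Sfi1 at 12.8 CPM against at most 8.11 in the other WT libraries). Without this library 7 genes other than EGFP were called after IRI, and all separated the other libraries. It lay inside the TG range at 1, Gm6969, with 20.4 CPM against 0.235 to 24.7 in TG and at most 0.205 in the other WT libraries. It lay outside the TG range at 6. At 3 of these it was inside the range of the other WT libraries (Ccn1 at 832 CPM against at most 493 in TG). At the others it was between the ranges or at the TG maximum (Gas1 at 16.8, Hspa1a at 999 and Hspa1b at 1350, against at least 17, 1250 and 1660 in the other WT libraries). These 6 genes were called near the threshold (edgeR adjusted p 0.0392 to 0.0475) in the libraries they separate, so a left-out TG library could fall outside their TG range. The immediate early score of 7.19 and red blood cell score of 4.73 of this library were above the highest TG scores of 6.89 and 3.45. All 6 TG IRI libraries held EGFP (1.17 to 6.31 CPM), so a swap with one of them lacks its partner; a mixture with RNA of a TG kidney stays open too, and no biological explanation was tested.

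Gsta2, the gene the genotype is named after, was not called higher in TG than in WT libraries in either sex or any condition, though its mean after NX was higher (111 against 70 CPM). Reads of the transgene counted under near-identical paralogs are argued against, since Gsta1, Gm10639 and Gm3776 held at most 7.95% of the summed CPM of the family in any TG or WT group of males and the family's log2 ratio was -0.89, 0.65 and -0.12 in no-surgery, NX and IRI males (exact permutation, p = 0.1, 0.5 and 0.669); reads discarded because they map to several places stay open. The labels do not state whether the construct carries Gsta2 coding sequence, so no rise of Gsta2 need follow from it. If it does, transgene RNA too low beside Gsta2 to be seen may account for the absent rise. With 1 transcript carrying both genes, EGFP per kb came to 11.6, 8.59 and 5.45% of the WT Gsta2 level per kb. These shares lie below the rises of 29.6, 56 and 32.2% that 2 SE correspond to. Low transgene RNA does not account for the lower level in TG males without surgery (50.6 against 96.2 CPM). Protein was not measured, and a biological difference of the genotype stays open as untested.

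Immediate early genes, and Hspa1a and Hspa1b among the heat shock genes, were lower in TG libraries than in libraries labelled WT after IRI. The heat shock list as a whole did not pass (score, exact permutation, adjusted p = 0.0505). The run of library numbers as the whole cause is argued against, since with run as a term the score differences were -0.49 ± 0.1 (early genes) and -0.49 ± 0.18 (heat shock), against -0.51 and -0.49 without it (exact permutation within the runs, p = 0.00833, the smallest it can give, and 0.0333), although with run as a block, which leaves fewer residual degrees of freedom, the gene calls ended (Hspa1a from -1.55 ± 0.24 to -1.42 ± 0.25, adjusted p 0.127 to 0.194 over the 12 genes). The library labelled WT that holds EGFP did not carry the difference, since the early gene score difference was -0.50 without it, against -0.51 with it. Leaving it out does not test it as a TG kidney. Its early gene score lay above all TG scores and above the lowest WT score of 6.95, so counted as TG it would narrow the difference. Red blood cells left in the kidney are argued against as the whole cause for Hspa1a and Hspa1b, if such cells hold more globin RNA than RNA of these genes, which was not measured. The 4 globin genes differed by 412 CPM, 17.8% of the 2320 CPM by which Hspa1a and Hspa1b differed. Fos, Jun, Junb, Egr1 and Ccn1 together differed by 1740 CPM. Other blood cells were not tested. A difference in the severity of injury, in infiltrating neutrophils or an effect of the genotype may each remain, and these data do not separate them.

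Among 98 tests for a single library far from its group, 10 were positive, and chance gives about 1 in 20. Gsta3 was at 86.5 CPM in WT IRI replicate 3 against 64.7 to 71.1 in the others. Orm1 was at 0.127 in the same library against 0 to 0.0377. Adrb3 was at 0.251 in WT IRI replicate 0 against 0 in the others, and Acvr1c at 0.251 in that library against 0 to 0.0317. The immediate early gene score was 6.95 in WT IRI replicate 2 against 7.19 to 7.28. The neutrophil marker score was 3.36 in WT IRI replicate 5 against 1.43 to 1.95. Acod1 was at 3.21 CPM in TG IRI replicate 4 against 0.0942 to 0.596. Atf3 was at 680 in TG IRI replicate 1 against 405 to 467. Acvr1c was at 0.565 in TG IRI replicate 0 against 0 to 0.154.

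Some genotype differences differed between the sexes or between IRI and NX by the interaction test. Msmo1 differed between the sexes by -0.98 on the log2 scale. With camera's preset correlation, 4 lists differed between the sexes, all toward lower in TG females: tubule injury markers (adjusted p = 0.0312), ferroptosis-related genes (0.0411), cell cycle genes (6.42e-05) and lymphocyte markers (0.0312). Between IRI and NX the genotype difference was shifted up for NRF2 targets (adjusted p = 9.02e-08), antioxidant enzymes (0.000174), ferroptosis-related genes (0.00838), proximal tubule genes (0.00838) and male-biased genes (0.000266). It was shifted down for immediate early genes (adjusted p = 2.27e-05), cytokines (0.0227), interferon-stimulated genes (0.00476), heat shock genes (0.0227), endothelial (0.0433), podocyte (0.00838) and thick ascending limb markers (0.000174). None of these lists kept its call with an estimated correlation; by fry only NRF2 targets passed (adjusted p = 0.0275).

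The counts were set beside those of other splits of the same libraries. For IRI against NX in WT, 1 of 84 splits, the real one, reached its 5952 genes (highest other 942). In TG 1 of 84 reached 5661 (highest other 3). Chance is argued against, though 1 of 84 is the smallest share such splits can give, without a correction for several comparisons. The other splits mix IRI with NX libraries, so the injury difference widens the spread within their groups and can lower their counts. The splits do not separate these groups from the order of library numbers. In WT all NX numbers precede all IRI numbers, and each no-surgery group holds consecutive numbers. The split with 942 genes set WT IRI replicates 0, 4 and 5 and the NX libraries against WT IRI replicates 1, 2 and 3, which points to a structure among these libraries. For TG against WT after IRI, 3 of 100 splits, drawn from 462, reached 12 genes. This share is narrowly under 0.05, without a correction for the several comparisons tested in this way. It also holds only if libraries can be exchanged across the runs of library numbers. With run as a block 0 genes passed, so chance is not clearly excluded. The highest other gave 407 genes; that split exchanged TG replicate 0 and WT replicate 3 and left the other 5 of each genotype in place, which points to a structure among the libraries beside genotype, and without WT replicate 3 109 genes were called. Its 18 lists were reached by 1 of 100 splits (highest other 17). Chance is not excluded for the interaction with sex (1 gene, reached by 10 of 100, highest other 20, and 4 lists, 94 of 100, highest other 13). Nor is it excluded for the interaction with injury (0 genes, 100 of 100, highest other 7, and 12 lists, 23 of 100, highest other 15). The number of lists called for IRI against NX cannot decide about chance (16 in WT, 20 of 84, highest other 20, and 11 in TG, 32 of 84, highest other 18). Other splits of these libraries still carry the large injury difference. Chance is not excluded for the male-higher genes after IRI either, whose camera p of 1.9e-05 was the smaller of the 2 sex-biased lists. In 42 of 100 splits, the real one included, the smaller camera p of the 2 lists was as low (smallest other 1.2e-15). The comparisons of 3 against 3 have 10 splits, too few for a share under 0.05. Their real gene counts and highest others were 1 and 3 (TG against WT, males), 8 and 0 (females), 4077 and 0 (females against males, WT), 4054 and 1 (TG) and 2 and 5 (NX). Their list counts were 8 and 12, 1 and 13, 14 and 13, 18 and 16, and 6 and 13 in the same order, and the smaller p of the sex-biased lists after NX was 0.155 against 0.000667.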

How the results depend on the processing

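Halved counts, the run block and the list tests without a named library were chosen after the data were seen; the other alternatives were planned. Over 599 named gene results, 9236 of 9848 alternative values kept their direction and side of the threshold, 495 lost the call, 103 gained one and 14 reversed; 65 uncalled changes of sign were counted among those kept, and 33 DESeq2 values without an adjusted p were left out. All 16 values of the Gsta2 group means under RLE and upper-quartile factors stayed within 1 SD. The gene counts of females against males and of IRI against NX stayed within 1.5-fold under every alternative but the 2-fold minimum, which gave 871 (WT) and 849 (TG) for sex and 2094 (WT) and 1990 (TG) for injury. For the small counts the cause was not tested unless fewer samples or genes explain it. TG against WT in no-surgery males (1 gene) became 15 without a count filter, 14 with DESeq2, 0 with limma-voom, and 1 to 2 on leaving out each replicate. In females (8) it became 19 with upper-quartile factors, 107 without a filter, 220 with DESeq2, 73 with limma-voom, 3 with the 2-fold minimum, 40 with the replicate block and 14 with halved counts, and 1 to 22 on leaving out each replicate. The interaction with sex (1) became 2 (upper quartile, robust edgeR or halved counts), 37 (no filter), 94 (DESeq2), 4 (limma-voom), 0 (2-fold) and 11 (replicate block), and 0 to 3. After NX (2) it became 127 (no filter), 45 (DESeq2), 1 (replicate block) and 0 (all 18 libraries), and 2 to 15. After IRI (12) it became 43 (no filter), 363 (DESeq2), 5 (2-fold, or replicate block), 22 (all 18 libraries) and 0 (run block), and 0 to 109. The interaction with injury (0) became 51 with DESeq2, and 0 to 1 on leaving out each replicate. DESeq2 gave more false calls in simulated data.

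Camera's list counts fell with an estimated correlation from 8 to 0 (TG against WT, no-surgery males), 1 to 0 (females), 14 to 5 (sex, WT), 18 to 4 (sex, TG), 4 to 0 (interaction with sex), 6 to 0 (NX), 18 to 1 (IRI), 16 to 5 (IRI against NX, WT), 11 to 7 (TG) and 12 to 0 (interaction with injury). With fry, which compares a list with no change and not with other genes, they became 0 in no-surgery males, females, the interaction with sex and NX, 1 after IRI and 1 for the interaction with injury. Without WT NX replicate 0 camera called 10 lists in TG against WT after NX. On leaving out each IRI replicate the score differences ran from 0.24 to 0.41 (injury markers), -0.49 to -0.23 (cytokines), -0.60 to -0.42 (heat shock), 0.12 to 0.20 (NRF2 targets) and -1.85 to -1.20 (neutrophil markers), and each of these passed without 1 library: injury markers and NRF2 targets without WT replicate 3, cytokines and neutrophil markers without TG replicate 4, heat shock without TG replicate 1. The immediate early gene score passed under all 14 alternatives (adjusted p 0.0108 to 0.0433). Without the 2 libraries farthest from the median Gsta2, r changed sign for neutrophil markers (0.11) and proximal tubule genes (0.31) in TG and injury markers in WT (0.88). The male-higher genes after IRI gave adjusted p = 0.538 with an estimated correlation. Leaving out each replicate, IRI against NX in WT ranged over -8.29 to 6.43 (Elovl3), -7.32 to 4.14 (Orm1), -10.64 to 4.69 (Adrb3), -6.48 to 11.28 (Ucp1), -6.18 to 8.14 (Plin1), -5.92 to 6.91 (Otop1), -5.72 to 2.45 (Cidec), -7.45 to 4.9 (Acvr1c) and -1.57 to 0.29 (Phlda3), the upper end always without WT NX replicate 0, and in TG over -3.85 to 0.27 (Cyp4a14). With limma-voom Ucp1 was 2.22, Plin1 0.68, Otop1 1.89 and Cidec 1.38. The labels do not pair the samples and shared replicate numbers gave r of -0.03 to 0.26, not above 0.1 in every pair, so the replicate block was kept as an alternative only. Depth limits the precision of genes at a few CPM or less, among them EGFP, Havcr1, Gm12735 and Gsta1.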

Other observations

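The combination of 4 comparisons was chosen after the results were seen.

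Single genes of further lists changed with IRI, while the lists of macrophage and endothelial markers did not pass (camera adjusted p = 0.738 and 0.605). In WT libraries the resident macrophage receptor gene Cx3cr1 fell 3.61-fold (1.17 ± 0.187 against 4.18 ± 1.2 CPM, adjusted p = 1.3e-05) while the lysosomal macrophage gene Cd68 rose 2.56-fold (5.55 ± 1.05 against 2.14 ± 0.069, adjusted p = 2.04e-05), with n = 6 and 3. The endothelial junction gene Cdh5 rose 2.36-fold (70.5 ± 16.2 against 29.5 ± 2.36, adjusted p = 1.27e-05). Ptgs2, which makes prostaglandins, rose 74.6-fold (12.6 ± 3.55 against 0.165 ± 0.024). The female-biased progesterone-metabolizing gene Akr1c18 fell 5.27-fold (4.07 ± 2.06 against 21.3 ± 6.56) and the male-biased steroid hydroxylase gene Cyp7b1 3.39-fold (69.3 ± 31.8 against 232 ± 36.4).

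The globin genes, summed, differed between TG and WT by -1.14 on the log2 scale in no-surgery males, 0.09 in females, -2.97 after NX and -2.79 after IRI (exact permutation, p = 0.6, 1, 0.1 and 0.00433; adjusted p = 0.0173 after IRI, and 0.1 is the smallest p for 3 against 3). The adjustment was over these 4 comparisons only, and the test was chosen after the values were seen. After IRI 5 of 6 TG libraries lay below all libraries labelled WT. The libraries labelled WT IRI replicates 4 and 5 held Gsta2 at 107 and 143 CPM, beside their higher mitochondrial share.

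Sfi1, Gm12735 and Patz1, the 3 genes called beside EGFP over 16299 genes when the 4 comparisons were combined, were higher in TG in all 4 and lie in a stretch of chromosome 11. The reason was not tested: the stretch was defined by these genes, and count tables hold no reads that join EGFP to chromosome 11.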
